A study of Mus musculus with 6 samples.

How the data were processed

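The data were expression arrays of soleus muscle, a small postural muscle of the calf, from C57Bl/6 mice. Per the labels, total RNA was isolated with the RNeasy kit from cryosections of the muscle, and 3 µg was used for each array. The labels describe each of the 6 samples as a control mouse and number them 1 to 6. They say no more about the individual samples, nor whether each array was of a separate mouse, so the spread between these samples may be partly technical. The p-values of single gene lists compare genes on the same arrays and do not measure the spread between samples. The other p-values rest on that spread. The titles also hold a short code that the labels do not explain, and it was not interpreted.

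The deposited table held 1 intensity value per probe and array for 223 probes, a small array directed at selected genes. Scanner, background correction and scaling are not given in the sources used here. The intensities were on a linear scale and fell below 0 for some probes on every array, the form that background subtraction gives. Array medians differed 4.15-fold and array sums 4.03-fold, so the deposited intensities had not been brought to a common level. The probe for 28S ribosomal RNA was deposited with 2 decimals and every other probe with up to 4 decimals. No gene coordinates are given because no genome build is named for the array.

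Probes were named through the platform annotation that goes with the table. A single gene was given for 205 probes, several genes for 0 probes, and no gene for 18 probes, which stayed unnamed. Of the 205 gene identifiers, 204 were found in the mouse gene table of the GRCm38.p6 assembly, used for names only, and 0 symbols changed. Probe sequences were not used here, so cross-hybridisation between related genes, such as the myosin heavy chains, was not checked.

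Intensities were brought to log2. Probes with an intensity above 0 on all 6 arrays were kept, which left 153 probes. Probes of the same gene were averaged after log2, which applied to the 2 probes of Igf1, and gave 145 named genes and 7 unnamed probes, 152 in all. Each array was then centred on its median over these 152. A level is therefore the log2 intensity relative to the median of its own array, and levels of different probes were not set against each other. The size of the most negative intensity on an array served as its noise bound, and a value below it has no reliable size. Such values above 0 stayed in the levels, SDs and tests as they were, so for a gene below the bound on some array these rest in part on background. Of the 223 probes, 106 lay above the bound on all 6 arrays and 47 on no array, and 12 were at or below 0 on all 6 arrays. Arrays give no counts, and their number and the signal over background are among the limits of the precision.

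With a single group there was no comparison between groups, and each result describes the spread among the 6 samples. Agreement between arrays was described with Pearson's r and Spearman's rho across genes, which are not independent replicates, for the 15 pairs of arrays. The spread of each gene was the SD of its centred log2 values. Genes that varied more than genes of like intensity were sought with limma 3.58.1 and statmod 1.5.0 in R 4.3.3. An intercept was fitted for each gene and a prior variance was estimated robustly with an intensity trend. A one-sided F test then compared each variance with its prior, with Benjamini-Hochberg adjustment over the 152 and a threshold of 0.05. The prior had 6.12 degrees of freedom.

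Gene lists of muscle pathways and of other cell types were tested where at least 3 members were measured, which held for 10 lists. The median SD of a list (two-sided) and the mean pairwise Pearson's r among its members over the 6 arrays (one-sided, higher) were set against 10000 random lists. In these each member was replaced by a random choice among its 40 nearest genes by level, and Benjamini-Hochberg adjustment covered the 10 lists. Such a permutation test describes these arrays, since genes of a list are not independent. Relations between the mean levels of 2 lists were tested two-sided over all 720 pairings of the 6 arrays, an exact permutation test. Of 8 relations planned, 4 had enough measured genes on both sides.

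The tests, the gene lists, the alternatives other than cyclic loess and the noise-bound filter, and the rule for named genes were fixed before the data were examined. By that rule, the text names the 8 genes with the largest and the 8 with the smallest SD, each gene past the threshold for excess spread, and the members with the largest and smallest SD of each tested list. Other genes named as examples were chosen after their values were seen. The alternatives were no centring, quantile normalization, removal of the dimmest genes (a share of 0.25), a looser filter of 4 arrays, an added pseudocount of 0.00065, each replicate left out in turn, and other measures, priors, tests and matching rules. Cyclic loess normalization and a filter at the noise bound were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

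The tests were tried on simulated data with the levels of these 152 genes. Genes were simulated as independent and normally distributed, with SDs on the intensity trend, and p-values of lists were adjusted over the simulated lists only. The rates may therefore differ for the measured arrays. With 15 genes changed, an SD multiplied by 3 was recovered in 42.7% of them and an SD multiplied by 6 in 88%, over 20 simulations. With no gene changed there were 0.1 false calls per simulation. A list simulated to co-vary at r = 0.7, above the means of the lists measured here except that of the fast contractile list, was called in 20 of 20 runs, a list with its SD doubled in 20 of 20, and an unchanged list in 1 of 20.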

Results

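Expression of 223 probes was measured on 6 arrays with RNA from soleus muscle of control C57Bl/6 mice. The labels do not say whether each array was of a separate mouse. The labels define 1 group and state no comparison, so the values describe gene levels in control soleus and their spread from sample to sample. Median intensities of controls 1 to 6 were 0.0161, 0.0143, 0.0241, 0.0593, 0.0205 and 0.0161. The summed intensities were 43.9, 45.9, 48.9, 125.2, 33.8 and 31.1. Intensities at or below 0 were found for 32, 67, 34, 37, 27 and 30 probes, and 143, 109, 153, 155, 163 and 166 probes lay above the noise bound. The 10 brightest probes of each array gave 76.2% to 83.9% of its summed intensity.

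Several transcripts of the contractile and metabolic machinery of muscle gave a signal above the noise bound on all 6 arrays. The slow myosin heavy chain Myh7 had a level of 6.97 ± 0.54 (log2 relative to the array median, SD, n = 6), and the oxygen store myoglobin, Mb, had 6.91 ± 0.42. The fast myosin heavy chains were also detected on all 6 arrays, with Myh2 at 4.99 ± 0.36, Myh1 at 4.68 ± 0.37 and Myh4 at 3.45 ± 0.21. The glycolytic enzymes Aldoa and Gapdh lay at 7.44 ± 0.26 and 7.19 ± 0.32, and Cox4i1, a subunit of cytochrome c oxidase, at 4.47 ± 0.25. Other metabolic genes lay below the array median, among them Ldha, a lactate dehydrogenase subunit, at -1.35, the glucose transporter Slc2a1 at -0.65 and the hexokinase Hk1 at -2.87. These levels carry the affinity of each probe and do not rank the transcripts. Across genes, Pearson's r between arrays had a median of 0.93 over the 15 pairs, from 0.858 for controls 1 and 5 to 0.982 for controls 3 and 4. Spearman's rho had a median of 0.919, from 0.809 to 0.982. The arrays differed in an ordered way. Pairs of control 1 or 2 with control 5 or 6 had the lowest Pearson's r, 0.858 to 0.887, while controls 5 and 6 had 0.970 with each other. The labels give no batch or order of processing to set beside this. Measures of the arrays set the same samples apart. Controls 1 and 2 had 143 and 109 probes above the noise bound, and controls 5 and 6 had 163 and 166. The 10 brightest probes gave 81.3% and 83.9% of the sum in controls 1 and 2, and 76.2% and 76.6% in controls 5 and 6. A technical source can therefore not be told from a difference between samples.

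The 8 genes with the smallest spread differed by at most 1.46-fold between the highest and the lowest array. Egfr, the epidermal growth factor receptor, had an SD of 0.11 and a fold of 1.25 between its highest and lowest array. The growth factor Tgfb1 had an SD of 0.11, and the fibroblast growth factor receptor Fgfr1 had an SD of 0.16. The growth hormone receptor Ghr followed with 0.17, the vascular endothelial growth factor receptor Kdr with 0.18, the angiotensin-converting enzyme Ace with 0.19 and the angiopoietin receptor Tek, which was above the noise bound on 5 arrays, with 0.20. Cpt1b, which carries fatty acids into mitochondria in muscle, had an SD of 0.19 at a level of 1.10. Over the 152 genes and unnamed probes, the median SD was 0.54 on the log2 scale, a fold of 1.45, with quartiles of 0.36 and 0.79. The SD was larger for dim genes, with a Spearman's rho of -0.446 between SD and level across genes, which are not independent replicates. Its median was 0.87 in the dimmest 0.25 of the genes and 0.45 in the brightest 0.25. The median SD was 0.94 without centring of the arrays.

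**Figure D1:**
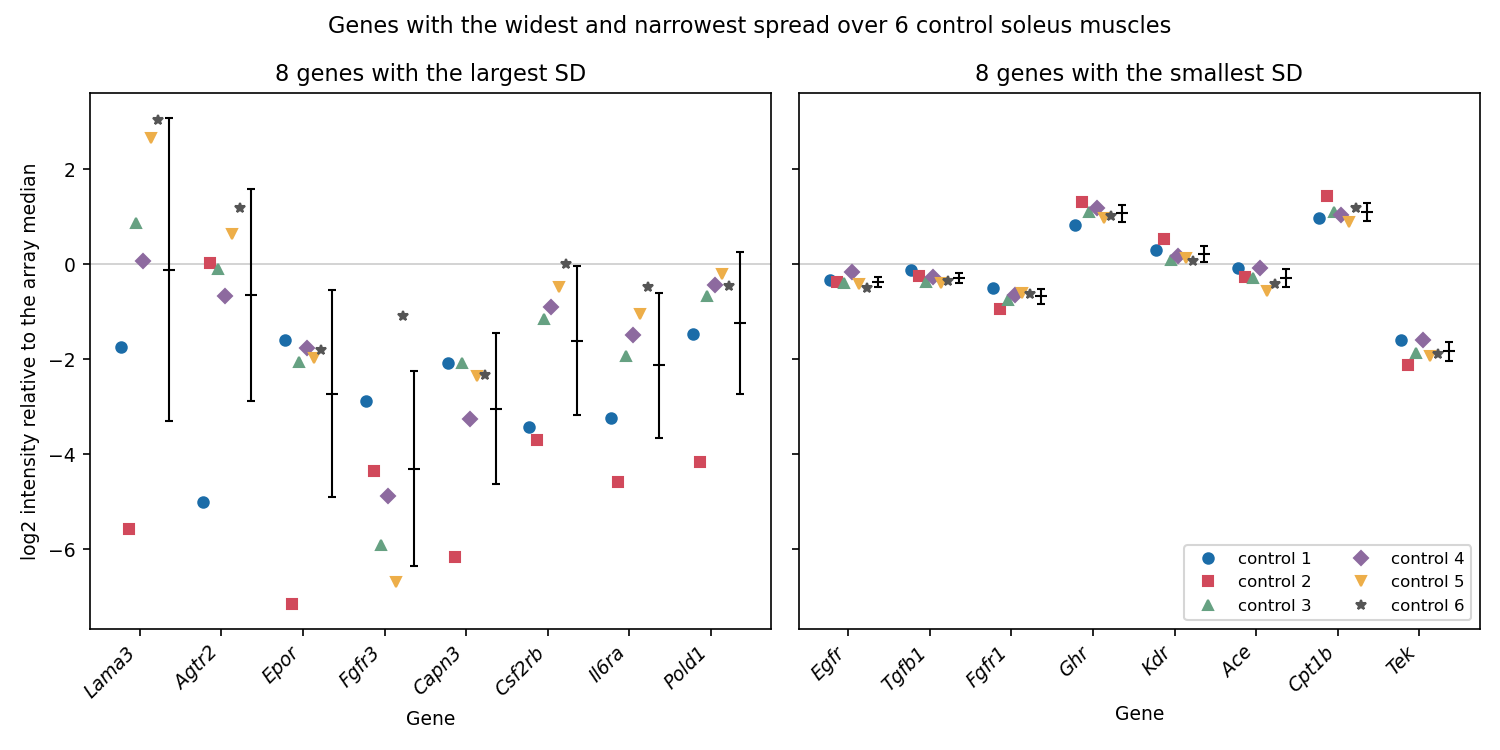
Levels (log2 intensity relative to the array median, vertical axis) of the 8 genes with the largest and the 8 with the smallest SD in each of the 6 control samples, 1 symbol per sample, with the mean and SD as bars. Lama3 (SD 3.20) and Agtr2 (SD 2.23) spread over several log2 units, with their lowest points below the noise bound, while Egfr and Tgfb1 (SD 0.11 each) spread least.

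The widest spread was that of Lama3, a laminin chain of basement membranes, and of Agtr2, the type 2 angiotensin receptor. Lama3 had levels of -1.75, -5.57, 0.88, 0.07, 2.65 and 3.04 in controls 1 to 6 and an SD of 3.20. The lowest of these, in control 2, lay below the noise bound, and with values raised to at least the bound the fold between the highest and the lowest array was 27.7. Agtr2 had levels of -5.01, 0.03, -0.09, -0.67, 0.63 and 1.19, and an SD of 2.23. Its lowest, in control 1, was also below the bound, and the highest array was at least 10.8-fold above it. With limma's prior variance and a one-sided F test these were the 2 of 152 past the threshold, with adjusted p = 0.00852 for Lama3 and 0.0496 for Agtr2, and 9 had an unadjusted p under 0.05. The other 6 of the 8 genes with the largest SD did not pass the test. They were the erythropoietin receptor Epor (SD 2.18, adjusted p = 0.703 in limma), the fibroblast growth factor receptor Fgfr3 (2.05), the muscle protease Capn3 (1.59), the cytokine receptors Csf2rb (1.56) and Il6ra (1.52), and the DNA polymerase subunit Pold1 (1.50). Fgfr3 lay above the noise bound on 1 array, Capn3, Csf2rb and Il6ra on 4, and Epor and Pold1 on 5. Without control 2, whose value was below the bound, the SD was 0.19 for Epor, 0.54 for Capn3 and 0.47 for Pold1. Without control 2 the SD of Lama3 was 1.97 and its adjusted p 0.846, and without control 1 the SD of Agtr2 was 0.71 and its adjusted p 0.829. Without replicate 1, 4 or 5 the only call was Lama3. The number of genes past the threshold was also 0 after quantile or cyclic loess normalization, with the looser filter, with the noise-bound filter, without robust estimation and without the trend, and 25 with a chi-square test against the median variance.

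Among the pathway lists, the genes of glucose uptake and glycolysis went up and down together over the samples. The mean pairwise r of the 10 measured members was 0.467, against a mean of 0.050 and a central 95% of -0.089 to 0.358 for random lists of like intensity (one-sided permutation p = 0.0076, adjusted p = 0.038). The glucose transporters Slc2a1 and Slc2a4 had mean r of 0.65 and 0.64 with the other members, the lactate dehydrogenase subunit Ldhb 0.66, the kinase Pgk1 0.62 and Gapdh 0.58. The transporter Slc2a3 and the hexokinase Hk1, which was above the noise bound on 4 arrays, had 0.12 each. Of the 10 members, 8 were lowest in control 5 and 5 were highest in control 1, while over all 152 genes 58 were lowest in control 5 and 51 highest in control 1. The median SD of the list was 0.35 against 0.51 for random lists (two-sided permutation p = 0.0238, adjusted p = 0.209), with members from 0.26 for Aldoa to 1.17 for Hk1, whose SD was 0.74 without replicate 2. The adjusted p for co-variation was 0.252 without replicate 5, where the excess of mean r over random lists was 0.130 against 0.416 with all samples. It was 0.058 without replicate 1, 0.071 after cyclic loess and 0.112 after quantile normalization.

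Genes of the extracellular matrix co-varied as well. The mean pairwise r of the 14 members was 0.263, against 0.018 and a central 95% of -0.062 to 0.188 for random lists (one-sided permutation p = 0.0070, adjusted p = 0.038). The matrix proteases Mmp14 and Mmp2 had mean r of 0.50 and 0.46 with the other members, the protease inhibitor Timp2 0.50, the integrin subunit Itgb1 0.45 and the laminin chain Lamc1 0.44. The glycoprotein Tnc, with -0.44, and the laminin chain Lama4, with -0.06, did not follow. In control 1, 8 of the 14 members had their highest level, while over all 152 genes 51 did. In a test chosen after the results were seen, the one-sided permutation p of this count was 0.017 for this list and array alone. Over all 60 pairs of a list with an array it was 0.241. The measured fibroblast markers were also highest in control 1, with Pdgfra, which is not in the matrix list, at -0.44 against -2.68 to -2.07 in the other samples, and Fn1, which is in it, at 3.01. The Fn1 level came from a single probe, and its other probe, above the noise bound on 0 arrays, was left out. The median SD was 0.42 against 0.53 for random lists, with adjusted p = 0.439 in the two-sided permutation test. It ranged over members from 0.11 for Tgfb1 to 1.28 for Mmp2, which was above the noise bound on 2 arrays and had an SD of 0.66 without replicate 1. The adjusted p for co-variation was 0.130 without replicate 1 and 0.117 without replicate 2, 0.0575 after cyclic loess, 0.112 after quantile normalization, 0.051 without centring and 0.073 with unmatched random lists. For both lists it also missed the threshold without replicate 3 or 4, with Spearman's rho and with the looser filter.

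The remaining muscle lists did not pass the test for spread or for co-variation. The 3 fast myosin heavy chains were each highest in control 1 and lowest in control 5, and their mean r of 0.812 gave an adjusted p of 0.150 in the permutation test, with a random mean of 0.208. Myh1 had the largest SD of the 3, 0.37, and Myh4 the smallest, 0.21, but without replicate 1 the SDs were 0.09 and 0.18. The excess of mean r over random lists was 0.604, and 0.318 without replicate 1. The 6 respiratory chain genes had a median SD of 0.35 against 0.51 for random lists (permutation p = 0.0418, adjusted p = 0.209) and a mean r of 0.399 (adjusted p = 0.159). Their spread ran from 0.25 for Cox4i1 to 0.86 for Tfam, the mitochondrial transcription factor, which was above the noise bound on 2 arrays and had an SD of 0.33 without replicate 1. Of the 10 genes of fatty acid handling, 8 were highest in control 2 and 6 lowest in control 5, and the regulators Ppara and Pparg were lowest in control 2. The list had a mean r of 0.278 (adjusted p = 0.150 in the permutation test) and a median SD of 0.49 (adjusted p = 0.958). The fatty acid carriers Cd36 and Fabp3 had SDs of 0.67 and 0.65, and the regulator Pparg had 0.86, or 0.53 without replicate 2. Without the dimmest 0.25 of the genes, and with the noise-bound filter, the fast contractile and fatty acid lists also passed for co-variation, with adjusted p of 0.0488 and 0.045 in the permutation test for each, and the fast contractile list passed without replicate 2 (adjusted p = 0.0242).

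Signalling, growth and cell cycle genes showed no excess co-variation. The mean r was 0.070 for the 20 vascular and hypoxia genes, 0.040 for the 14 myogenic and growth genes and -0.13 for the 5 cell cycle and DNA maintenance genes. The adjusted p-values in the permutation test were 0.414, 0.480 and 0.849. The 3 proteolysis genes had a mean r of 0.020 (adjusted p = 0.613) and the 5 endothelial markers -0.123 (adjusted p = 0.831). Median SDs were 0.54 for the vascular, 0.55 for the myogenic, 0.83 for the cell cycle, 0.88 for the proteolysis and 0.33 for the endothelial list, with adjusted p in the permutation test of 0.587, 0.830, 0.607, 0.439 and 0.411. Within the vascular list the SD ran from 0.16 for Fgfr1 to 2.18 for Epor. In the myogenic list it ran from 0.38 for the insulin receptor Insr to 1.28 for the myostatin antagonist Fst, in the cell cycle list from 0.35 for the retinoblastoma gene Rb1 to 1.19 for the cyclin Ccnd1, and in the proteolysis list from 0.53 for the calpain inhibitor Cast to 1.59 for Capn3. These upper ends rested on control 2, where the value was below the noise bound, and without it the SD was 0.19 for Epor, 0.37 for Fst, 0.40 for Ccnd1 and 0.54 for Capn3. Of the 10 lists, 0 passed for spread, with 2 at an unadjusted permutation p under 0.05. Without replicate 1 the fast contractile list passed, with a median SD 0.436 times that of random lists and an adjusted p of 0.048.

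**Figure D2:**
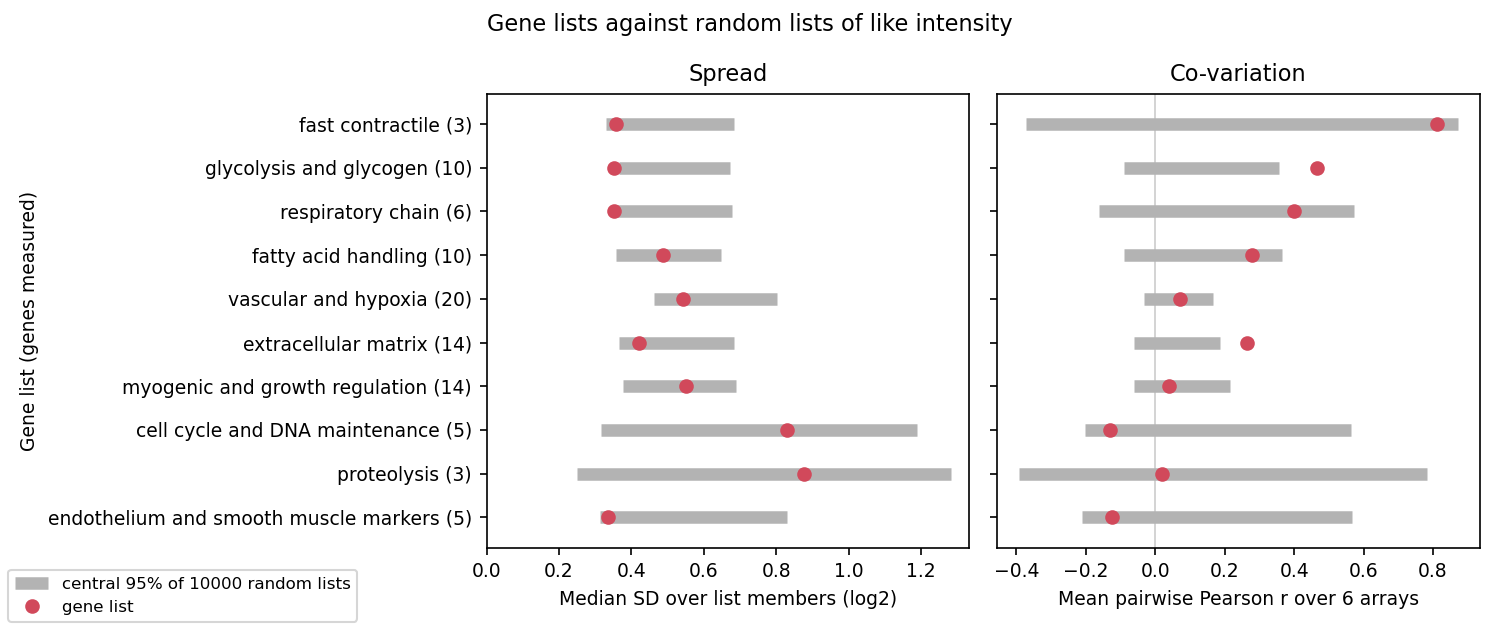
Median SD of log2 intensity over list members (left) and mean pairwise Pearson's r over the 6 arrays (right) for 10 gene lists, as points, with the central 95% of 10000 random lists of like intensity as bars and the number of measured genes in brackets. The points for glycolysis (0.467) and extracellular matrix (0.263) lie above their bars on the right.

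Some lists had under 3 measured members and were not tested. These were the slow contractile list with Myh7 and Mb, the citric acid cycle list with Pdha1 (3.80 ± 0.50, SD, n = 6) and Mdh2 (2.85 ± 0.47), the developmental contractile list with the intermediate filament gene Des (4.17 ± 0.45), and the stress list with Jun. Of the markers of other cell types, Fabp4 of adipocytes had a level of 2.26 ± 0.68, Pdgfra and Fn1 stood for fibroblasts, and Myod1 and Myog for satellite cells. The calcium, blood and immune, and peripheral nerve lists had 0 measured members.

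Mean levels of oxidative genes followed those of fatty acid handling over the 6 samples, without passing the test after adjustment. The oxidative score, the mean over citric acid cycle and respiratory chain genes, had r = 0.911 with the fatty acid score (exact permutation p = 0.0361, adjusted p = 0.0806 over 4 relations) and a rho of 0.829 (exact p = 0.0583, adjusted p = 0.233). Without controls 2 and 5, the samples farthest from the median of the oxidative score, r was -0.07, so the relation rested on those samples. The vascular and oxidative scores had r = -0.896 (exact permutation p = 0.0403, adjusted p = 0.0806) and a rho of -0.486 (exact p = 0.356, adjusted p = 0.356), and r was 0.960 without controls 2 and 5. The glycolysis and fast contractile scores had r = 0.770 (exact permutation p = 0.103, adjusted p = 0.137) and a rho of 0.657 (exact p = 0.175, adjusted p = 0.322), with r = -0.136 without controls 5 and 1. The oxidative and glycolysis scores had r = 0.597 (exact permutation p = 0.197, adjusted p = 0.197) and a rho of 0.6 (exact p = 0.242, adjusted p = 0.322), with r = 0.457 without controls 2 and 5. Several vascular genes, such as Epor and Pdgfb, were below the noise bound in control 2, and with the noise-bound filter the vascular relation had r = -0.691. It turned positive without centring of the arrays, with r = 0.773, and was -0.334 after cyclic loess and -0.573 without replicate 2. The relation of oxidative genes with glycolysis was -0.05 without replicate 5, -0.000465 after cyclic loess and 0.420 after quantile normalization. It passed the exact permutation test without centring (r = 0.947, adjusted p = 0.0444), without the dimmest genes (0.944, 0.0222), with the noise-bound filter (0.979, 0.0111) and with list medians (0.949, 0.00556). That of oxidative with fatty acid genes passed without centring, with list medians and without replicate 3, and that of glycolysis with fast contractile genes passed without centring and was -0.263 after quantile normalization and 0.020 after cyclic loess. Without centring both scores of a relation carry the brightness of each array, and array medians differed 4.15-fold. The passes without centring therefore cannot be told from array brightness and are no evidence for a relation. The labels give no batch, so no relation could be repeated within one.

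**Figure D3:**
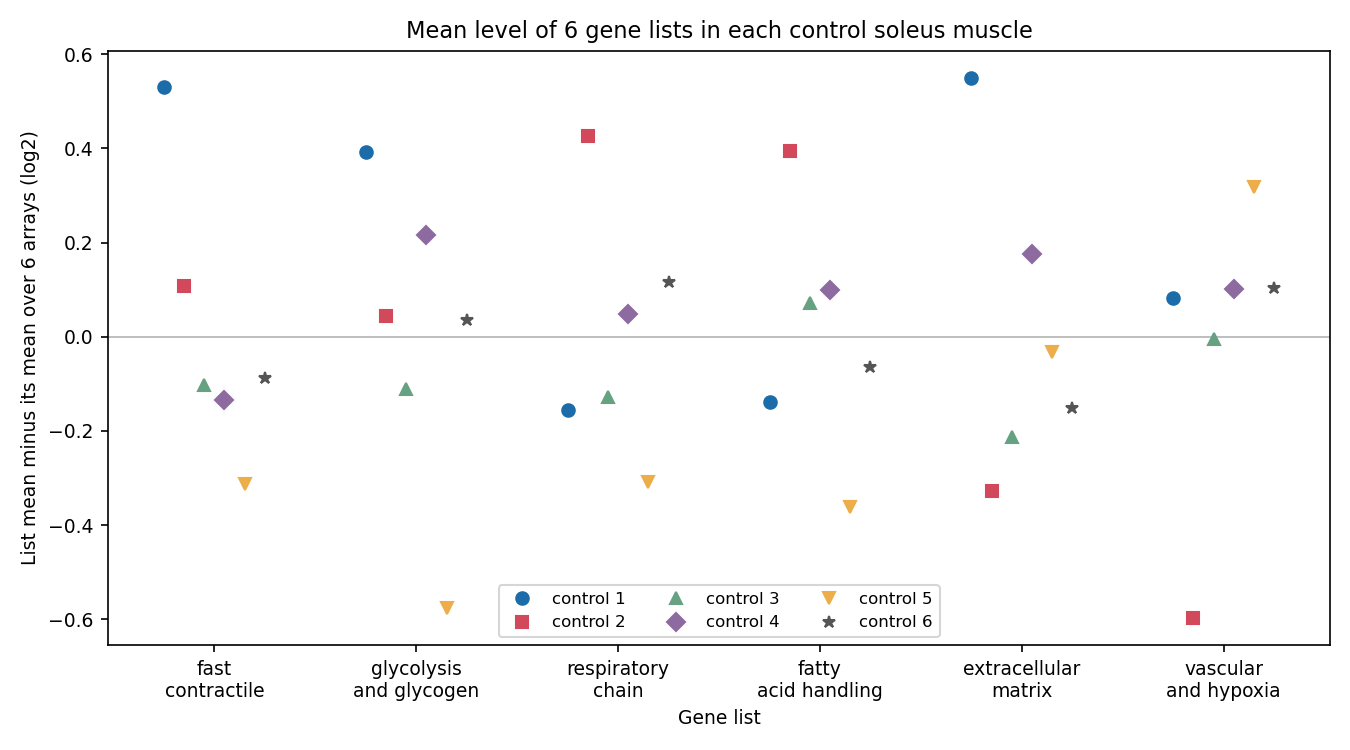
Mean level of the genes of 6 lists in each control sample, as the difference from the mean of that list over the 6 arrays (log2, vertical axis), 1 symbol per sample. Fast contractile and glycolysis genes lay highest in control 1 and lowest in control 5, respiratory chain and fatty acid genes highest in control 2 and lowest in control 5, and vascular genes lowest in control 2. Several vascular genes, such as Epor and Pdgfb, were below the noise bound in control 2.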

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

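The tests of background, scaling and intensity-dependent differences, and the spot-fault and endothelial-cell tests on Igf1 were chosen only after the results were seen. The tests of probe position and of scaling for Igf1 were written before they were run, but for patterns already found in these data. That of scaling for Igf1 used cyclic loess, which was added after the data were seen. The labels put all 6 samples in 1 group, so the design names no biological difference to test, and the only biological explanation tested was the share of endothelial cells for Igf1.

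The spread of Lama3 and Agtr2 stood apart from genes of like intensity, with Agtr2 at -5.01 in control 1, below the noise bound and far from the other samples. Relative to the noise bound, Lama3 had 0.048 times the bound in control 2 and 73.5 times in control 6, and Agtr2 had 0.147 times in control 1 and 20.4 times in control 6. With every value raised to at least the noise bound, the SD of Lama3 was 1.96 and that of Agtr2 1.19, against a 95th percentile of 0.99 over all genes, and over the arrays above the bound the SDs were 1.96 and 0.71, which argues against background signal as the whole source for Lama3 and leaves it open for Agtr2. After quantile normalization the SDs were 2.76 and 1.98, down from 3.20 and 2.23 but above the 95th percentile of 1.24. These SDs still hold the values below the bound, and both genes had been picked for the widest spread. The comparison therefore does not decide whether scaling contributes. Both calls were lost after quantile normalization, with adjusted p of 0.305 and 0.543 in limma. With the prior degrees of freedom held at 6.12 in place of 3.65, Lama3 passed (adjusted p = 0.0140) and Agtr2 did not (0.0565). After cyclic loess both calls were also lost (0.640 and 0.835), and both passed with 6.12 degrees (0.00295 and 0.0162). Scaling stays open, and a true difference in the amount of these transcripts between the samples may be one of the open explanations.

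The glycolysis and extracellular matrix lists co-varied more than random lists. After cyclic loess, which removes intensity-dependent differences between arrays, the mean r went from 0.467 to 0.201 for glycolysis and from 0.263 to 0.188 for the matrix, against upper limits of random lists of 0.190 and 0.141. With the smaller correlations the adjusted p missed the threshold (0.071 and 0.0575 in the permutation test), so such array differences stay open for both lists. Probes whose names share a number had a mean r of 0.164 against 0.034 for other pairs, and over members with numbers at least 2 apart the mean r was 0.246 against an upper limit of 0.187 for the matrix list and 0.337 against 0.340 for glycolysis. No source used here describes the array layout, and the letters in the names were not tested, but the value argues against shared or neighbouring numbers as the source for the matrix list (65 of 91 pairs), and leaves them open for glycolysis, with 13 of 45 pairs left.

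Igf1, insulin-like growth factor 1, was highest in control 5 on both of its probes, with levels of 2.69 and 2.75, but its spread did not pass the test in limma (adjusted p = 0.911 over 152 genes), and its gap over range of 0.558 did not pass Dixon's test, so chance over many genes is open. The gap to the next array was 1.18 and 1.13 on the probes, against a median SD of 0.54 over genes, which argues against a fault in 1 spot. After cyclic loess the gap was 1.28 against a median SD of 0.50, so this normalization did not remove it. Igf1 had been picked for its high value in control 5, so the comparison does not decide whether scaling of the array contributes. The endothelial markers had a median rise in control 5 of 0.19 over the other arrays, with Pecam1 at 1.24, Flt1 at 0.66, Cdh5 at 0.19, Kdr at -0.09 and Tek at -0.11. The median lay below the bound of 0.38 set for a rise of 1.53 in Igf1. These markers did not move together over the arrays (mean r -0.123), so their median does not measure the share of endothelial cells. More endothelial cells in control 5 therefore stay open. A difference in Igf1 transcript between the samples remains as a hypothesis, found and tested on the same 6 arrays.

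For the genes and measures given next, a single sample stood apart, with a gap to the nearest sample larger than Dixon's test allows at the 95% level. Chance gives about 1 in 20 such cases, and 19 of the 152 genes, 12.5%, had one. Control 2 gave the lowest values for Epor (-7.16), Capn3 (-6.16), Pold1 (-4.16), Fst (-3.70) and Ccnd1 (-4.16), all below the noise bound of that array, 0.0062, so these values have no reliable size. Control 2 was far above the other samples for Mb (7.71). Control 1 was high for Myh1 (5.41), Itgb1 (3.27), Lamc1 (2.06) and the fibroblast marker Pdgfra (-0.44), which was above the noise bound on 5 arrays. Its low value for Tfam (-4.75) was below the noise bound, as it was on 4 of the arrays. The laminin chain Lamb2 was high in control 4 (0.67) and the ribosomal protein gene Rps29 low in control 5 (4.60). The mean level of the vascular list was low in control 2 (-1.48). Several of its members were below the noise bound there, among them Epor, Pdgfb, Nos2 and Hif1a, so this low mean rests in part on background. Of the arrays as a whole, control 4 stood apart by its median intensity of 0.0593 and its sum of 125.2, and control 2 by its 67 probes at or below 0.

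Of the genes left out because an intensity was at or below 0 on some array, 8 lay above the noise bound on 3 or more arrays. The highest multiples of the bound were 4.65 for Cyct in control 5, 4.61 for Pola1 in control 5, 2.96 for Igfbp2 in control 5, 2.89 for Top3a in control 6, 2.82 for Cd44 in control 1, 2.04 for Vegfc in control 5, 1.78 for Agt in control 5 and 1.52 for Igfbp3 in control 5.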

How the results depend on the processing

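Cyclic loess and the noise-bound filter were chosen only after the data were seen. No paired analysis was possible because there was only 1 group. Signal over background limits the dim genes, of which many lay below the noise bound on some arrays. The agreement between arrays stayed within its spread under each alternative run. Over single named genes, 410 values of spread kept their side of the threshold, 10 gained it and 16 lost it, and a reversal was not defined for them. Of the values for co-variation of single lists 106 kept it, 5 gained it, 18 lost it and 18 reversed, and for list spread 135 kept it, 1 gained it and 11 reversed. Except where stated, the cause of a change was not tested.

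The median SD of 0.54 became 0.94 without centring and 0.41 as a median absolute deviation, and 0.45 to 0.58 without single replicates. The 2 genes with excess spread became 0 with quantile normalization, the looser filter, cyclic loess, the noise-bound filter, a prior that was not robust and no intensity trend, 1 (Lama3) with a pseudocount, 25 with the chi-square test, and 0 to 2 without single replicates, with 0 without replicate 2 and 1 (Lama3) without replicate 1, 4 or 5. The noise-bound filter removes both genes by its construction. The 0 lists called for spread became 0 to 1 without single replicates, the 1 being the fast contractile list without replicate 1. The 2 lists called for co-variation became 1 without centring (glycolysis), 1 with unmatched random lists (glycolysis), 4 without the dimmest genes, 4 with the noise-bound filter, and 0 with quantile normalization, the looser filter, cyclic loess and Spearman's rho. They were 0 to 2 without single replicates, with 0 without replicate 1, 3 or 4 1 (matrix) without replicate 5, and fast contractile and glycolysis without replicate 2. The 0 relations past the threshold became 3 without centring (all but vascular with oxidative), where array brightness enters both scores. They became 1 (oxidative with glycolysis) without the dimmest genes, 1 (the same) with the noise-bound filter and 2 (oxidative with glycolysis and with fatty acid) with list medians. Without single replicates they were 0 to 1, the 1 (oxidative with fatty acid) without replicate 3.

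The r of oxidative with glycolysis genes became 0.947 without centring, 0.944 without the dimmest genes, 0.979 with the noise-bound filter, 0.949 with list medians, -0.000465 after cyclic loess, 0.0429 with the looser filter, and -0.0525 to 0.762 without single replicates, lowest without replicate 5. For oxidative with fatty acid genes it was 0.990 without centring, 0.949 with list medians, and 0.620 to 0.966 without single replicates. For glycolysis with fast contractile genes it was 0.984 without centring, -0.263 after quantile normalization, 0.0201 after cyclic loess and 0.347 with list medians. For vascular with oxidative genes it was 0.773 without centring, -0.334 after cyclic loess, -0.691 with the noise-bound filter, and -0.940 to -0.573 without single replicates, weakest without replicate 2.

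Reversals otherwise fell on tests that the list did not pass with the main settings. The ratio of list SD to random SD crossed 1 for the vascular list (1.02 without centring, 1.01 unmatched), for fatty acid handling (1.05 with the looser filter, 1.01 with a pseudocount, 0.836 to 1.29 without single replicates) and for the myogenic list (0.964 with the looser filter, 0.936 to 1.15 without single replicates). The excess of mean r over random lists changed sign for 4 lists. For the myogenic list it was -0.00374 without centring, -0.00212 without the dimmest genes, -0.0261 with the looser filter, -0.0141 after cyclic loess, -0.00656 with Spearman's rho and -0.0693 to 0.0731 without single replicates. For the endothelial markers it was 0.120 without centring, 0.0121 after quantile normalization, 0.0443 without the dimmest genes and 0.0354 after cyclic loess. For the vascular list it was -0.0217 after quantile normalization and -0.0363 to 0.0857 without single replicates. For proteolysis it was 0.101 after quantile normalization, 0.0148 with the looser filter, 0.0298 with a pseudocount, 0.243 with Spearman's rho and -0.215 to 0.525 without single replicates.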

Other observations

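The tests on fatty acid genes and on the Igf1 probes reported here were chosen only after the result was seen. Genes that take up and burn fatty acids often stood highest in control 2. Of the 10 measured members, 8 had their highest level there, among them the fatty acid translocase Cd36 at 4.80, while the regulators Ppara and Pparg had their lowest there, at -0.28 and -3.46, the latter below the noise bound. Against random lists of like intensity the one-sided permutation p was 0.0029 for this list and array alone. The list and the array were picked from the data, and over all 60 pairs of a list with an array the one-sided permutation p was 0.0519, so a random choice of genes is not excluded. In that test proteolysis in control 3, with 1 member highest there, had the smallest p that the random lists can give, 1e-04, because none of them drew Capn3, the only gene that was highest in control 3. Over all 152 genes 41 were highest in control 2, and after cyclic loess 6 of the 10 members were. Myoglobin and the slow myosin Myh7, which are not in the list, also had their highest levels in control 2, 7.71 and 7.67, and so did the adipocyte marker Fabp4, at 3.39 against 1.59 to 2.53 in the other samples. Other bright probes were highest in control 2 as well, among them those of 28S ribosomal RNA, Aldoa and Ttn. Gapdh, Ldhb and Des were highest in control 1. A high level in control 2 was therefore not particular to genes of oxidative muscle or fatty acids.

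The fast myosin heavy chains Myh1, Myh2 and Myh4 were highest in control 1, at 5.41, 5.58 and 3.72, and lowest in control 5, at 4.40, 4.62 and 3.16. Control 5 also held the lowest level of Myh7, 6.15, and of Mb, 6.49. Many other bright genes were lowest in control 5, among them Gapdh, Aldoa, Cox4i1, Ldhb, Ttn and Rps29. The bright 28S ribosomal RNA probe and the unnamed probe 1C were lowest in control 4. Low levels in control 5 were therefore not particular to contractile genes. In control 5 Pecam1, an adhesion molecule of endothelial cells, had its highest level, 2.94, and Igf1 reached 2.72 as the mean of its probes. Over the 6 arrays the Igf1 probes had r = 0.850 (exact permutation p = 0.0486) and a rho of 0.943 (exact p = 0.0167), and r was 0.906 without the samples farthest from the median.

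Controls 3 and 4 lay near the middle of the group. Control 3 held the highest level of 1 gene and the lowest of 7, and control 4 the highest of 18 and the lowest of 5, while control 1 held the highest of 51 and control 5 the lowest of 58. Across genes these arrays had r = 0.982 with each other, although their sums were 48.9 and 125.2. The intensity of the 28S ribosomal RNA probe was 2.66, 3.52, 3.55, 5.13, 3.83 and 1.57 in controls 1 to 6. The hormone-sensitive lipase Lipe, left out because of intensities at or below 0, lay above the noise bound in controls 2 and 4, with intensities of 0.0072 and 0.0156.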
